A study of Pinus canariensis with 9 samples.

How the data were processed

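The series consisted of 9 two-colour Agilent arrays hybridised with RNA from Canary Island pine (Pinus canariensis), 1 array for each of 3 trees at each of 3 stages called R0, R1 and R2. Per the labels' protocols, the trees were 5 years old, resprouting was induced by wounding the stem, and 200 ng of total RNA was labelled per sample. Each array carried RNA from newly formed resprouts with the phloem and meristem around them in one channel, and RNA from resprout-free phloem of a remote part of the same tree in the other. The labels do not say what separates the stages beyond the sampling date. Trees 1 and 12 had the resprout RNA in Cy3 and tree 9 had it in Cy5 at every stage, so that 6 arrays ran one way and 3 the other, and a dye effect cannot be told apart from what is particular to tree 9. The labels give both channels the tissue "phloem (control)" and speak of xylem in the extraction, and the source names were followed instead.

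The scanner files hold the intensity of each spot in both channels as deposited, extracted with Feature Extraction 10.7.3.1 per the file headers. The mean signals and the median local backgrounds were used without the scanner software's own correction. The log10 ratio of Cy5 over Cy3 that the authors' scanner software computed was also deposited in these files, and between 6.46% and 8.67% of the spots of an array carry exactly 0 there. The authors deposited a value table of log2 ratios as well, made with limma per the submitters' processing notes, which give no version. Set against the scanner files over all spots that are not controls, each of its columns correlated with the normalised log2 Cy5/Cy3 ratio at an absolute r between 0.988 and 0.996. Its scale is that of log2, its columns have medians of 0 (R0 tree 1), 0.02 (R0 tree 9), -0.01 (R0 tree 12), -0.01 (R1 tree 1), 0.01 (R1 tree 9), 0.02 (R1 tree 12), 0.02 (R2 tree 1), 0.01 (R2 tree 9) and 0.03 (R2 tree 12), and how it was centred is not given in the sources used here. Its direction was resprout over control for 8 arrays. For the R0 array of tree 12 it had the opposite sign to the one that the channel labels give.

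Signals were corrected with limma 3.58.1 in R 4.3.3 by the normexp method with an offset of 50, and log2 ratios were normalised by loess within each array, with control spots and non-uniform outlier spots at weight 0. Each array held 61339 spots, of which 59961 were not controls, and these belonged to 19952 probes. Of the probes, 19937 had 3 spots and 15 had 10. The spots of a probe were averaged without non-uniform outliers, of which an array had between 115 and 426, and no spot was saturated. A probe was tested if more than 50% of its spots were well above background in either channel on at least 3 of the 9 arrays, which held for 17265 probes. Ratios were turned to resprout over control from the channel labels. Where a probe was not well above background in one channel on all arrays of a stage, its ratio was given as a lower bound, the mean of the brighter channel over the higher of the lowest signal well above background and the probe's own signal, from signals after loess and Aquantile, which stays open to dye bias because the swaps are not balanced.

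One limma model held 1 mean per stage over all 9 arrays, with no dye or tree term, and each stage mean was tested against 0 and against the other stages by the two-sided moderated test, with Benjamini-Hochberg adjustment over probes within a comparison and a threshold of 0.05. The number of arrays limits the precision, and the median standard error of a stage mean was 0.21 on the log2 scale. The tests, the samples, the naming rule and most alternatives were fixed before the data were examined. Trees pair the arrays of different stages by design. The deviations of same-tree arrays from their stage means correlated between -0.28 and 0.35 over 9 pairs (mean 0.01), and those of different trees between -0.31 and 0.32 over 18 pairs. The model with tree as a block is therefore given as an alternative. The other alternatives were other background corrections and normalisations, the deposited log2 table, other filters on dim probes, a random tree block, a dye term, the second slide, each stage on its own, a 2-fold minimum and each array left out. The first slide held 8 arrays and the second 1, so a slide term amounts to leaving that array out.

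All spots that are not controls are described as unknown in the files, and nothing used here pairs the probes with genes, except that 46 probes carry 1 of 24 gene names in the design's name column. Of these names 22 were tested, through 38 probes, each name represented by its probe with the highest mean signal. The 27 gene lists fixed beforehand, among them photosynthesis, cell cycle, lignin, defence, meristem regulators and the markers of phloem, xylem and periderm, were written as patterns for gene descriptions. With no descriptions in the files they could be matched only to the gene names, where a single one, tubulin and kinesin, met 1 name. The names abbreviate, so that names such as Ppterrpl2mod and Ppterrpl30 were not met by the pattern for ribosomal proteins. By the rule set beforehand no list was tested, which says nothing on whether members are on the array. By the naming rule, at most 2 probes each way with the largest ratios among those past the threshold and of one sign in all 3 trees are named, or, where nothing passed, those with the smallest p. For the probes with gene names, the 3 with the smallest p each way are named at each stage.

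The fit was tested on simulated ratios of the 17265 probes with the spread of the real ones, of which 200 were changed. For the R2 mean, 33 of 68 probes changed by 1 on the log2 scale were called, 57 of 66 changed by 2 and 63 of 66 changed by 4, with 11 calls among unchanged probes. For R2 minus R0 the calls were 14, 44 and 55 in the same order, with 6 among unchanged probes. The simulated noise was normal, independent between probes and of equal spread on all arrays for a probe. The real arrays differed in spread, with an SD of the log2 ratios over probes between 0.36 and 0.90. These rates therefore hold for the simulated setting alone. Figures were drawn with matplotlib.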

Results

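The 9 arrays measured gene expression in resprouts of Canary Island pine, a conifer that forms new shoots from the stem after injury, against phloem of the same tree away from the wound. Trees 1, 9 and 12 were sampled at stages R0, R1 and R2, with 1 array per tree and stage. Median signals were between 512.4 and 889.3 in the resprout channel and between 363 and 990.7 in the control channel, and between 79.8% and 85.8% of spots were well above background in the resprout channel. The ratios of 2 spots of a probe correlated between 0.811 and 0.961 within an array. Probes are named by their identifiers, since nothing used here pairs them with genes.

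The resprout profiles of R1 and R2 resembled each other to a varying degree. Their log2 resprout/control ratios, correlated across the 17265 tested probes, which are not independent replicates, gave r between -0.06 and 0.57 over the 15 pairs, and only the pair of tree 1 at R1 and R2 lay below 0. The R0 array of tree 1 correlated between 0.18 and 0.50 with the 6 arrays of R1 and R2. The R0 array of tree 9 correlated with no other array above 0.03. The R0 array of tree 12 correlated at -0.81 with that of tree 1, which had the same dye orientation, and between -0.46 and -0.07 with the 6 later arrays. The deposited value table carries this array with the opposite sign to its channel labels. The direction of the R0 comparison is therefore not settled. Values are given as labelled unless stated otherwise, and counts that involve R0 also with that array turned. The conflict was noticed in these same ratios, and the turn brings the R0 arrays of trees 1 and 12 together. A lower p or a higher count with the array turned is therefore no separate support.

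**Figure D1:**
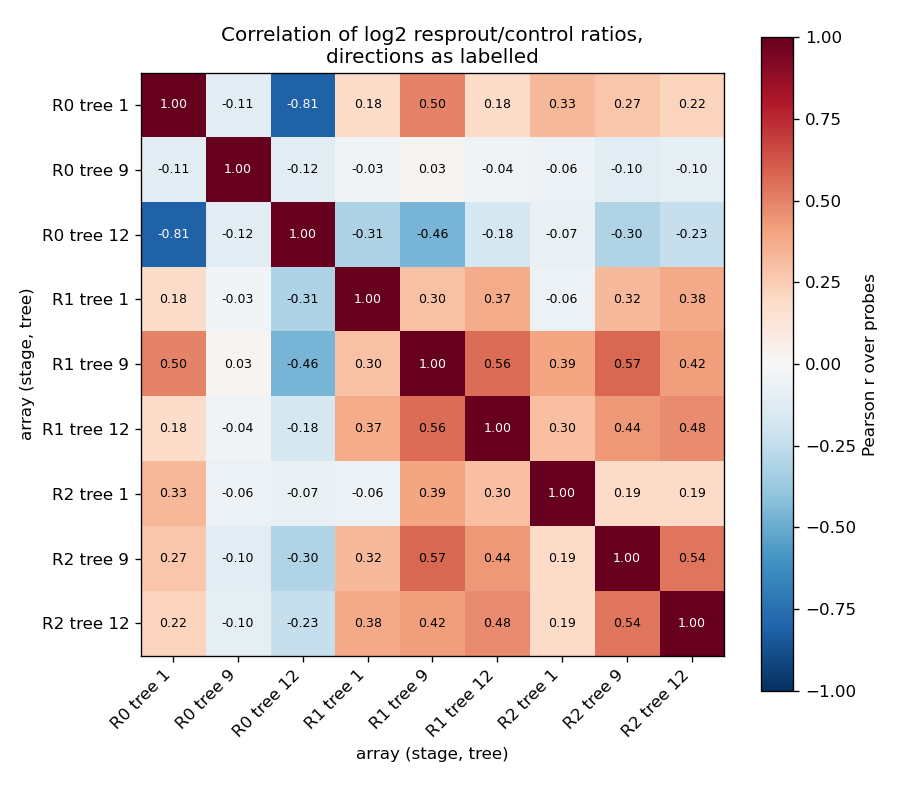
Pearson correlation across 17265 probes of the log2 resprout/control ratios of each pair of the 9 arrays, both axes listing stage and tree, with directions as labelled. The R0 array of tree 12 has negative values throughout, down to -0.81 with R0 tree 1, and the R0 array of tree 9 lies near 0 with all others.

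The comparison of resprouts with control phloem at R2 asked which transcripts differ between the resprout sample and remote phloem at the last stage. The resprout sample also held the phloem and meristem around the resprouts of a wounded stem. At every stage, tissue make-up and a local response to the wound therefore cannot be told apart from resprouting. By limma with Benjamini-Hochberg adjustment, 30 probes passed, 22 higher and 8 lower in resprouts, and all 30 had the same sign in 3 of 3 trees and at least a 2-fold ratio. The shared sign is no separate support, since passing left almost no room for a tree of the opposite sign. CUST_16542_PI427606162 was highest, with a log2 ratio of 6.61 ± 0.57 (SD, n = 3, adjusted p = 0.0199). CUST_1898_PI427606222 had a log2 ratio of 6.21 ± 0.66 (SD, n = 3, limma adjusted p = 0.00138). Among the lower probes, CUST_16656_PI427606162 had -3.13 ± 0.41 (SD, n = 3, limma adjusted p = 0.0276) and CUST_486_PI427606162 had -2.12 ± 0.17 (SD, n = 3, limma adjusted p = 0.0177). In the control channel at R2, CUST_16542_PI427606162 was well above background on 2 of 3 arrays and CUST_1898_PI427606222 on 1, so that their ratios rest in part on signals near background. The same holds for CUST_19939_PI427606162, CUST_4007_PI427606222 and CUST_2172_PI427606222 (2 of 3 arrays) and for CUST_387_PI427606222 and CUST_3705_PI427606222 (1 of 3). A further 8 of the higher probes, all with an identifier ending in PI427606222, were not well above background in the control channel on any R2 array, and the bounds on their ratios were between 2.79-fold and 22.9-fold. The higher probes had ratios between 1.46 and 6.61 on the log2 scale and the lower ones between -3.13 and -1.03.

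Of the 22 higher probes, 18 carried an identifier ending in PI427606222, which marks a sublist of 2036 of the 17265 tested probes (11.8%). The other 4 came from the remaining 15229 probes (Fisher's exact test, two-sided, p = 8.32e-14, the smallest of 5 sublists of at least 100 tested probes, Benjamini-Hochberg adjusted p = 4.16e-13), a test that takes probes as independent. The camera test in limma sets the mean moderated t statistic of the sublist against that of the other probes. It was run without ranks, so a few extreme probes can move it. At R2 camera gave the sublist an adjusted p of 0.0195 with a preset correlation of 0.01 between probes, and of 0.136 with the estimated one. The call of the sublist as a whole thus held with the preset one alone. PI427606166 was called lower at R2 in the same way (camera adjusted p = 0.0210 and 0.131). At R1 the preset correlation called PI427606166 and PI427606199 lower (camera adjusted p = 0.0219 and 0.0216) and not PI427606222 (0.0688), and the estimated one called none. The median log2 ratio of all tested probes of PI427606222 at R2 was 0.047. The 18 probes of PI427606222 called higher had median log2 ratios of 2.92, 4.93 and 2.87 in trees 1, 9 and 12 at R2 and of 0.61, 2.52 and 1.58 at R1. In the control channel 13 of these 18, including the 8 without control signal, were not well above background on every R2 array. The medians at R2 were therefore also computed with the control signal raised to at least the lowest one well above background. They were then 2.81, 4.64 and 2.87 in the same order, though a floor this low could change them little. Their medians at R0 as labelled were -0.24, 0.30 and -0.12, the last of which changes sign with that array turned. Of the 8 lower probes, 1 belonged to this sublist. What the sublist holds is not stated in the files. The sublist was singled out after the values were seen.

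The R2 count depended on the R0 arrays, which enter through the shared estimate of spread. It was 110 (54 higher, 56 lower), including all 30, with the R0 array of tree 12 turned, and 151, including all 30, without the 3 R0 arrays. With tree as a block 15 probes passed, all higher, of which 13 were among the 30. Single arrays decided it as well. The count was 86, 13 and 60 without the R0 array of tree 1, 9 and 12, 2 without the R1 array of tree 12, and 92, 2 and 1 without the R2 array of tree 1, 9 and 12. CUST_1898_PI427606222 was called at R2 under every alternative in which it was tested, with an adjusted p of at most 0.0359. The other named probes were less stable. CUST_16542_PI427606162 lost its call in 4 of 25 alternatives (adjusted p of up to 0.169), CUST_486_PI427606162 in 6 of 25 (up to 0.129, and 0.0576 with the tree block), and CUST_16656_PI427606162 in 11 of 24 (up to 0.217, 0.0959 with the tree block and 0.102 with the scanner software's ratio).

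**Figure D2:**
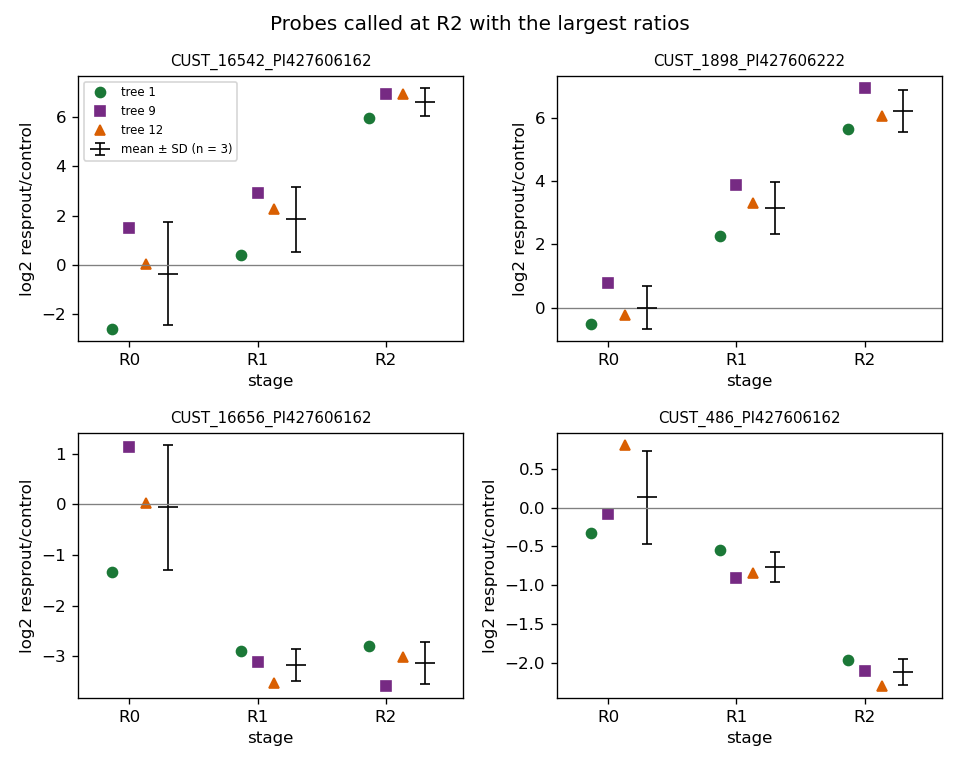
Log2 resprout/control ratio (vertical axis) at stages R0, R1 and R2 (horizontal axis) of the 4 probes named at R2, with a point per tree and a black bar for the mean ± SD of 3 trees, directions as labelled. CUST_1898_PI427606222 lies at -0.00 at R0, 3.14 at R1 and 6.21 at R2, and the R2 means of the 2 lower probes are -3.13 and -2.12.

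At R1, no probe passed by limma, with 646 at an unadjusted p under 0.05 and a smallest adjusted p of 0.158. These 646 are below a share of 0.05 of the 17265 tested probes, the share expected without any difference. The 30 probes called at R2 all had the same sign of the mean ratio at R1, and 24 of them, 18 higher and 6 lower, had an unadjusted p under 0.05 there. Both stage tests use the same estimate of spread for a probe and the same 3 trees. Probes picked for passing at R2 thus tend to a small p at R1 too, and this is no separate support. The shared sign was not set against that of all probes. CUST_16656_PI427606162 had a log2 ratio of -3.18 ± 0.32 (SD, n = 3, limma adjusted p = 0.158), much as at R2. It passed at R1 in 3 of its 24 alternatives (limma adjusted p between 0.0177 and 0.9997), and not with tree as a block (0.518). CUST_1898_PI427606222 had 3.14 ± 0.82 (SD, n = 3, limma adjusted p = 0.158). CUST_3705_PI427606222 had 1.99 and CUST_14510_PI427606162 had -1.49. With tree as a block 1 probe passed, CUST_1898_PI427606222 (adjusted p = 0.00712, between 0.00226 and 1.00 over its alternatives). A fit of the 3 R1 arrays alone called 31, 10 higher and 21 lower, and without the R0 array of tree 1 a single lower probe passed. With the R0 array of tree 12 turned, no probe passed and 1065 had an unadjusted p under 0.05.

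At R0 as labelled, no probe passed by limma and 39 had an unadjusted p under 0.05, also below the share of 0.05 expected without any difference. The probes with the smallest p were CUST_14138_PI427606162 and CUST_9978_PI427606162 among the higher, with log2 ratios of 1.19 and 0.75, and CUST_193_PI427606166 and CUST_8786_PI427606162 among the lower, with -0.82 and -0.59, none of them past the threshold (limma adjusted p = 1.00 for each). With the array of tree 12 turned these ratios were 0.77 and 0.34 for the former pair, and 0.15 for CUST_193_PI427606166, which changed sign, and -0.51 for CUST_8786_PI427606162. With the array of tree 12 turned, 2 probes passed, both higher, and 3622 had an unadjusted p under 0.05. The 2 that passed were CUST_5606_PI427606162, with a log2 ratio of 3.54 ± 0.88 (SD, n = 3, limma adjusted p = 0.0406), and CUST_19003_PI427606162, with 2.30 ± 0.50 (SD, n = 3, limma adjusted p = 0.0312). In the control channel at R0, so turned, the former was well above background on 2 of 3 arrays and the latter on 1. Their ratios thus rest in part on signals near background. With a tree block or a dye term added to the turned fit, limma called 0 probes, with 3200 and 3372 at an unadjusted p under 0.05. The turned counts and p-values are no support for an R0 effect. The turn sets the ratios of trees 1 and 12, opposed at r = -0.81 as labelled, in one direction. No probe passed in the same direction at all 3 stages, as labelled or turned.

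The differences between stages asked whether the resprout/control ratio changed from one stage to the next. From R0 to R2, 1 probe passed by limma. CUST_1898_PI427606222 rose from a log2 ratio of -0.00 ± 0.68 to 6.21 ± 0.66 (SD, n = 3 each), a difference of 6.21 with a standard error of 0.52 (adjusted p = 0.0232), higher in 3 of 3 trees. At R0 its signal was near background, well above it on 2 of 3 arrays in the resprout channel and on 1 in the control channel, with a mean log2 signal of 6.51 in both, so that the R0 ratio and the size of the difference are not exact. Tree as a block gave 5 probes including this one (adjusted p = 0.000853, between 0.000299 and 0.217 over its alternatives). Its call was lost with the scanner software's ratio (limma adjusted p = 0.0939) and without the filter on dim probes, where 0 probes passed. It was also lost on leaving out any 1 of 6 arrays, those of trees 9 and 12 at R0, tree 12 at R1 and all 3 trees at R2, where 0 probes passed. Without the R0 array of tree 1, 9 probes passed. With the R0 array of tree 12 turned, 8 probes passed, 6 higher and 2 lower. CUST_1898_PI427606222 was one of them, with a difference of 6.05 (limma adjusted p = 0.0158), and CUST_2956_PI427606222 had a difference of 5.34 and CUST_17681_PI427606162 one of -3.78 (limma adjusted p = 0.0252 and 0.0190). The resprout signal of CUST_2956_PI427606222 at R0, so turned, was well above background on 1 of 3 arrays, so the size of its difference is not exact.

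From R0 to R1 and from R1 to R2 no probe passed by limma as labelled or turned, with 372 and 226 probes at an unadjusted p under 0.05 as labelled and 1580 and 361 turned. All but the 1580 are below a share of 0.05 of the 17265 tested probes, the share expected without any difference. CUST_16656_PI427606162 had a difference of -3.11 from R0 to R1 and CUST_1898_PI427606222 one of 3.14, or -3.10 and 2.98 with the array of tree 12 turned. From R1 to R2 the latter had a difference of 3.07, CUST_5351_PI427606162 one of 1.77, CUST_7799_PI427606166 one of -1.72 and CUST_18861_PI427606162 one of -1.97. None of these differences passed as labelled (adjusted p = 1). Without the R2 array of tree 1, 1 probe passed from R1 to R2. An effect called at R2 and not at R1 is thus not shown to differ between these stages.

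In the fit of all 9 arrays none of the 22 gene names passed at any stage, over all probes or adjusted over the list alone, as labelled or turned, by limma. At an unadjusted p under 0.05 there were 0 at each stage as labelled, and with the R0 array of tree 12 turned 4 at R0, 2 at R1 and 0 at R2. At R1 the smallest p belonged to D38245.1 among the lower names, with a log2 ratio of -0.84 ± 0.85 (SD, n = 3, limma adjusted p = 0.622 over the list), and to CT581130 among the higher, with 1.94 ± 0.29 (SD, n = 3, limma adjusted p = 0.622 over the list). CT581130 had log2 ratios of 2.00, 1.62 and 2.19 in trees 1, 9 and 12 at R1, and in a fit of the R1 arrays alone, without the spread of its R0 values (SD of 3.41), it passed over all probes (adjusted p = 0.0435, between 0.0435 and 1 over its alternatives). PptereIF4, named for a translation initiation factor, had 0.34 and PpterERD3 0.45, while CT574796 had -0.47 and Ppterrpl2mod, named for a ribosomal protein, -0.21. At R2 the names with the smallest p were PpterUbiquitin (0.29), PptereIF4 (0.27) and Ppterrd21 (0.38) among the higher, and PpterERD3 (-0.43), Ppteralfatubulin, named for the cytoskeletal protein alpha tubulin (-0.64), and Ppterrpl2mod (-0.28) among the lower.

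At R0 as labelled the gene names with the smallest p were PthGA3PDH (0.62) and PsGA3PDH (0.54), named for the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, and PpterUbiquitin (0.18) among the higher. Among the lower they were PcontortaActin (-0.40), PscpGA3PDH1 (-0.14), whose probe sequence is that of PscpGA3PDH2 as well, and PsitcheIF4B2 (-0.08). This order depended on the array of tree 12. With it turned PthGA3PDH had -0.80, PsGA3PDH -0.77, PpterUbiquitin -0.15 and PscpGA3PDH1 0.38, all of the opposite sign, while PcontortaActin had -1.49 and PsitcheIF4B2 -0.25. The R0 means as labelled hid opposite values of trees. PcontortaActin had log2 ratios of -3.36, 0.52 and 1.63 in trees 1, 9 and 12 as labelled, and CT581130 had 3.17, -0.63 and -3.63. The smallest p at R0 with the array turned belonged to other names. Ppteralfatubulin had a mean of -1.17 ± 0.74 and Ptactin1 one of -1.14 ± 0.96 at R0 (SD, n = 3, limma adjusted p = 0.0894 over the list for both), and CT581130 had 2.06 ± 2.34 (SD, n = 3, limma adjusted p = 0.135 over the list).

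**Figure D3:**
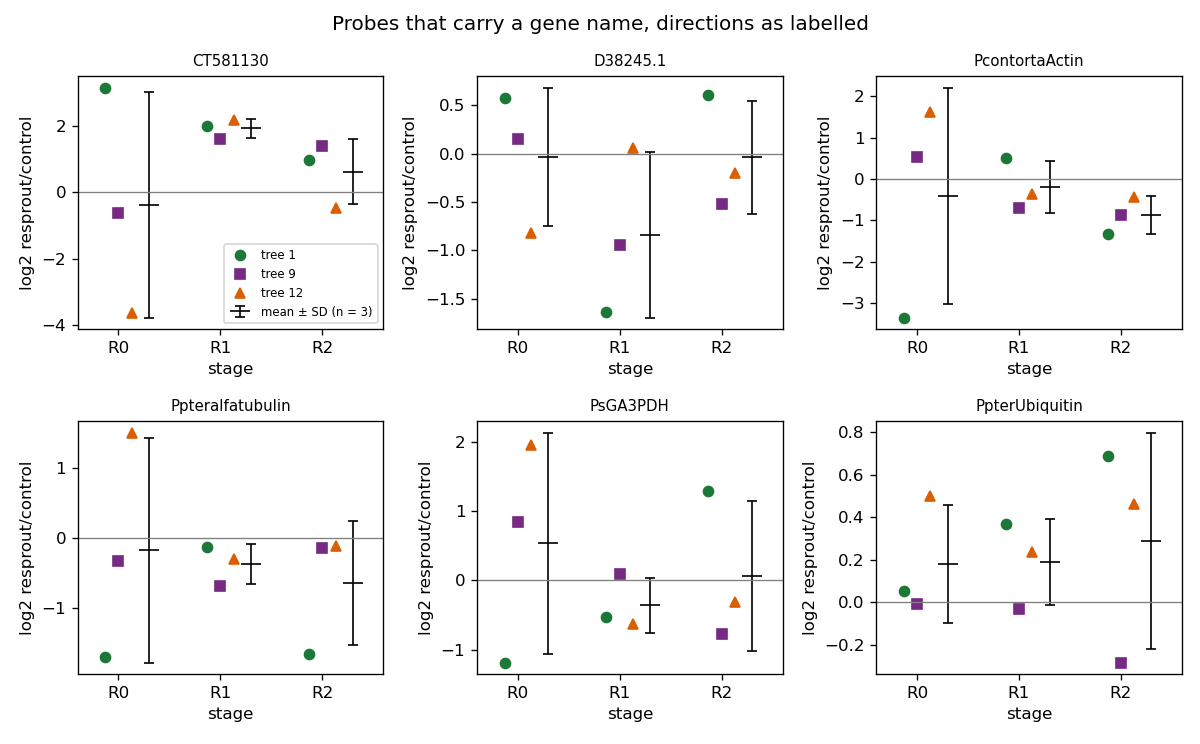
Log2 resprout/control ratio (vertical axis) at stages R0, R1 and R2 (horizontal axis) of 6 probes that carry a gene name, chosen after their values were seen, with a point per tree and a black bar for the mean ± SD of 3 trees, directions as labelled. Trees 1 and 12 lie on opposite sides of 0 at R0 for CT581130 (3.17 and -3.63) and PcontortaActin (-3.36 and 1.63).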

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

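The tests of the opposite R0 arrays, of the R0 array of tree 9 and of a control channel near background, and the check of the brightness split, were chosen after the results were seen, and the other tests of the sublist were set before theirs.

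As labelled, a single probe had a ratio that differed between stages, while 8 did from R0 to R2 with the R0 array of tree 12 turned, 5 with tree as a block and 17 with both. CUST_1898_PI427606222 was higher in resprouts by 6.21 more on the log2 scale at R2 than at R0, and by 6.05 more with the array turned, against R0 signals near background in both channels. Of the 10 splits of those 6 arrays into 3 and 3, 3 gave at least 1 probe, the real one included, and the highest of the others gave 1. These 10 splits are too few for a share under 0.05. The same holds for R1 minus R0 (0 probes, 10 of 10 splits as many, highest other 0) and R2 minus R1 (0 probes, 10 of 10 splits, highest other 1). For a stage mean there are 4 ways to turn its 3 arrays, also too few. At R2 the real one gave 30 probes and the highest of the others 0, so that 1 of 4 gave as many. At R1 it gave 0 and the others at most 0, and at R0 it gave 0 and the others at most 2, so that 4 of 4 did in each.

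Control spots meant for spiked RNA gave signal on the R0 array of tree 1. Of its 350 E1A control spots, 28.0% were well above background in Cy3 and 57.1% in Cy5, against at most 1.14% and 1.71% on the other 8 arrays. Of its 420 ERCC control spots, 13.1% were well above background in Cy5, against at most 2.38% elsewhere, while in Cy3 0.714% were, against at most 0.952% elsewhere. Its negative controls had a median of 124.4 in Cy3 and 62.8 in Cy5, against at most 100.2 and 39.5. Without this array 86 probes were called at R2 in place of 30. The count also rose without arrays that lacked such signal, to 92 without R2 tree 1 and 60 without R0 tree 12. The rise is thus not particular to this array. Groups of 3 arrays were not tested for outliers.

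The first pattern weighed is the opposition of trees 1 and 12 at R0. An exchange of the array between trees is argued against by the tree signature, 300 probes that separate the trees at R1 and R2, with which the array correlated at 0.892 or more in both channels for tree 12 and at most -0.31 for another tree. A dye bias common to both arrays would make their Cy5/Cy3 ratios correlate above 0, and r was -0.81. Channels exchanged against the label may account for it, since 0 of the 6 R1 and R2 arrays correlated above 0 with the array as labelled, and the deposited table carries it turned. A true difference between trees at R0 was not tested and stays open, as these later arrays were also those on which the conflict was noticed.

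The second pattern is the rise of probes of sublist PI427606222 in resprouts at R2. Dye bias is argued against, since the 36 sublist probes over 1 on the log2 scale in trees 1 and 12 had a median of 3.81 in tree 9, labelled the other way, and 35 of them lay above 0. Ratios inflated by a control channel near background are argued against as the whole cause for 5 of the 18 called probes. These 5 were well above background in both channels on every R2 array and had log2 ratios between 1.73 and 5.74. All 18 were well above background in the resprout channel on every R2 array. With the control signal raised to at least the lowest one well above background, their median log2 ratio was 3.46 (lowest 1.48), against 3.55 without. That lowest signal is so low that the raise could change the ratios little, and the highest stayed at 6.21. It therefore decides nothing for the other 13. The size of single ratios near background stays open. A test set beforehand compared the brighter 50% of probes by mean signal, where 0 of 538 in the sublist and 2 of 8094 elsewhere were called higher (Fisher's exact p = 1). This is the outcome set beforehand for inflation. The mean is over both channels and all stages, so a probe with low signal outside the R2 resprouts is dim by it whether its rise is real or inflated. By their R2 resprout signal 14 of the 18 probes, against 0 by mean signal, were in the brighter 50%. The split therefore cannot tell the 2 apart. A single RNA source of fixed composition, such as another cell type or organism, cannot be told apart from a shared programme, since the shift of the resprout signal of the 18 probes from R1 to R2 had an SD over probes of 0.51, 0.79 and 0.90 in trees 1, 9 and 12. The lowest of these is too wide for probes that move as one and too narrow for the spread set beforehand as evidence against it.

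The third pattern is the lack of relation of the R0 array of tree 9 to the others. Noise of the spots is argued against by the correlation of 0.811 between 2 spots of a probe on this array. An exchange between trees is argued against by its correlation of at least 0.857 with the signature of tree 9 in both channels, against at most -0.24 for another tree. What was sampled from this tree at R0 stays open and was not tested.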

How the results depend on the processing

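The turned array, its combinations and the fit without R0 were chosen after seeing the data. The count of probes shared by all 3 stages was 0 throughout, which was fixed, since under each alternative at least 1 stage had no call. At R2, the 30 probes became 48 with the scanner software's log ratio, 105 with the deposited values, which turn the R0 array of tree 12 (59 higher, 46 lower), 10 with probes well above background on all 9 arrays (15729 tested), 15 with tree as a replicate block, 1 with the slide as a block, 3 with the arrays of the stage alone, 110 with the turned array, 51 turned with the replicate block, 90 turned with a dye term, and 151 without the R0 arrays (55 higher, 96 lower). With a dye term as labelled the count was close, at 31 (26 higher, 5 lower), but only 24 of the 30 were among them. The 48 with the scanner software's ratio also held 24 of the 30. The share of higher calls, 73.3%, was 56.2% with the deposited values, 100% with the replicate block, 39.5% without R0 tree 1 (34 higher, 52 lower) and 35.9% without R2 tree 1 (33 higher, 59 lower). Leaving out each array gave 1 to 92. The lowest were 1 without R2 tree 12, 2 without R1 tree 12 and 2 without R2 tree 9, then 13 without R0 tree 9, and the highest were 60 without R0 tree 12, 86 without R0 tree 1 and 92 without R2 tree 1. At R1, 0 became 1 with the replicate block, 1 with a dye term, 31 with the stage alone, 3 turned with the block, 1 turned with a dye term and 1 without the R0 arrays (0 to 1 leaving out arrays). At R0, 0 became 2 with the deposited values and 2 turned (0 to 0 leaving out arrays). R1 minus R0 went from 0 to 1, and R2 minus R1 from 0 to 3, in the turned replicate block only, apart from 0 to 1 for the latter leaving out arrays. R2 minus R0, 1 probe, became 2 without background correction, 11 with the deposited values, 0 without a filter, 0 with the filter on all 9 arrays, 5 with the replicate block, 0 with the slide, 8 turned and 17 turned with the block (0 to 9 leaving out arrays). The cause of these changes was not tested. No named value past the threshold changed sign. In 26 cases a named value below the threshold changed sign, in 30 a call was lost and in 10 one was gained. The alternatives set for gene lists were not run, since the files hold no gene descriptions to match the lists to. Ratios of probes near background in one channel are limited by the signal there.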

Other observations

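All values in this part were computed after the data were examined. Counting probes with at least a 2-fold ratio of one sign in all 3 trees, with no test, gave 54 higher and 54 lower at R1, and 68 higher and 83 lower at R2. Turning any 1 of the 3 arrays gave at most 6 such probes at R1 and 33 at R2, against 108 and 151. At R0 there were 0 as labelled, 51 (32 higher, 19 lower) with the array of tree 12 turned, and 43 at most with that of another tree turned. The ratios had one sign in all 3 trees for 6.14% of probes at R0 as labelled, 35.8% at R0 with the array of tree 12 turned, 39.8% at R1 and 30.1% at R2, against 25% by chance. At R0 the ratios of trees 1 and 12 correlated at -0.81 as labelled, so the turn itself gives these 2 trees one sign for most probes. The 51 probes and the 35.8% with the array turned therefore show no agreement of 3 trees at R0. Between R1 and R2, 14 higher and 9 lower probes were shared, against 0.213 and 0.260 for independent lists. The stages share the 3 trees and the dye orientation of each, so their lists are not independent and some excess could come from that. With the array turned, R0 and R1 shared 3 higher and 1 lower, and R0 and R2 shared 0 of either. At R2 the sublist PI427606222 held 34 of the higher and 0 of the lower, while PI427606162 held 30 and 51 and PI427606166 held 3 and 29. These sublists hold 11.8%, 57.4% and 25.9% of the tested probes in the same order, so the 51 lower probes of PI427606162 are near its share by size.

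The mean signal of both channels differed more often between stages than between trees. In a limma model of the mean log2 signal with tree and stage, 993 of 17265 probes passed for stage and 344 for tree after Benjamini-Hochberg adjustment. Each stage was hybridised once per tree, and stage here also carries what the controls of that stage share.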
